A study of Lacticaseibacillus casei str. Zhang with 12 samples.

How the data were processed

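The samples were 12 total RNA preparations of the strain Lacticaseibacillus casei Zhang, each hybridised to 1 array. They fell into 6 groups of 2 arrays, set by the absence or presence of fermented milk and by 3 sampling times. Per the labels, cells were grown in MRS broth, a rich medium for lactic acid bacteria, at 37 °C for 18 h. Without milk, the cells were put directly into simulated gastric juice of pH 2.5. With milk, they first fermented 11% skim milk with 1.5% glucose to pH 4.5, and this milk was then mixed into the gastric juice. Samples were taken after 3 h in gastric juice, and after 4 h and 8 h in simulated intestinal juice of pH 8.0. The arms therefore differed in the medium in which the cells had last grown as well as in the milk that was present during incubation. The series' design text calls the 2 samples of each group biological replicates, and whether a replicate number marks the same culture at all 3 times is not given in the sources used here.

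Per the labels, RNA was extracted with TRIzol and a column kit, 2 µg were amplified and labelled, and the dye of every array was Cy3. Per the file headers, the arrays were scanned in 1 channel and read with Agilent Feature Extraction 10.5.1.1, which subtracted a fitted background and gave each spot a processed intensity on a linear scale. These deposited intensity values were the starting point here. The authors also deposited a table of log2 values per probe, which the series' design text calls normalized expression values. The log2 scale was found by setting the table against the scanner values of the same array, with Pearson's r across probes of 0.958 to 0.991. Its 12 columns had near-identical quantiles and were not centred per probe: the column medians were 5.17, 5.17, 5.17, 5.17, 5.17 and 5.16 without milk and 5.22, 5.22, 5.22, 5.22, 5.22 and 5.21 with milk. The method that gave those equal quantiles is not given in the sources used here.

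Each array held 14998 non-control spots of 6763 probes. Of these, 6740 probes had 2 spots and 23 had 66 spots, and every probe was 60 bases long. All 6763 probes carried the description "Unknown" and a numbered identifier. The gene table given for a related assembly matched 0 of the identifiers, so probes are reported by identifier and number. For the same reason the gene lists fixed in advance (among them stress proteins, transporters, peptidases, sugar use and the ATPase) and the alternative that merges several probes of a gene were not run. No probe had all of its spots flagged as outliers on any array, and no spot was saturated. Between 50 and 113 spots per array were flagged and left out. Control spots were left out of the tests.

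Spots of one probe were averaged as log2 processed intensity. The main setting subtracted each array's 75th percentile over all non-control probes. A probe was called well above background on an array when the scanner software set that flag on at least 0.5 of its spots. A probe was tested when it was well above background on both arrays of at least 1 group, which left 5041 probes. The test was limma's lmFit and eBayes on all 12 arrays with 1 mean per group, which left 6 residual degrees of freedom, and Benjamini-Hochberg adjustment within each comparison at 0.05. The average milk effect used milk and time as additive terms, 6 arrays against 6. Fold changes are on the log2 scale, and the error given is limma's standard error. Group values are means ± SD of 2 arrays. Signals given for a probe are processed intensities averaged on the log2 scale over the arrays of a group without scaling, while fold changes are on the scaled values. The number of arrays limits the precision of every value.

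The tests, groups, alternatives and the rule for naming probes were fixed before the data were examined. The rule took probes past the threshold whose arrays did not overlap between the groups, and which were well above background on both arrays of the brighter group, in order of log2 fold change. With no gene names, at most 2 rising and 2 falling identifiers were named per comparison. For the differences of milk effects the overlap condition was not used. Where a probe was not well above background on any array of the dimmer group, its change is a bound. It is given as at least N-fold, from the bright group's mean against, per array, the higher of the probe's own value and the lowest value among probes well above background. The lowest such value is not a detection limit that holds for every probe, and a bound moves with the scaling. The words "at least" therefore hold only under this rule and on the scale named. These bounds are on the main scale, and were computed again under the other scalings after the values were seen.

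Several steps were added after the values were seen. The probe numbers were divided into 4 consecutive sets by an optimal partition of detection on the arrays without milk alone, with a minimum length of 20 probes and a penalty of 20. Penalties of 10 and 40 gave the same ends. Because the share of detected probes differed between arms, the 75th percentile fell on a different part of the distribution with milk than without. The same holds for the median. Without milk, 46.6% to 49.8% of probes were well above background, and the median processed signal was 6.82 to 16.7, against 209 to 451 with milk. Median scaling therefore set background without milk against signal with milk, which lowers changes with milk on that scale. A further scaling therefore used the 75th percentile over the 2866 probes that were well above background on all 12 arrays, of which 2643 were in the second set, 91 in the first, 88 in the third and 44 in the fourth. The 2806 tested probes of the second set were fitted again alone on this scale, and are called values relative to the probes detected on all arrays. Those values show change relative to other detected probes, not change in the amount of RNA per cell. Since most of the scaling probes were in the second set, its median change and its balance of rises and falls on this scale were largely set by the scaling. The naming rule was applied to this fit as to the others.

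Replicates were compared before they were averaged, and no pair held identical values. The variance of the difference between replicate arrays was set against the scatter of the spots of each probe on 1 array. This ratio was between 0.425 and 0.919 in 5 groups and 6.50 without milk at 8 h. Spots at the same position share position effects on both arrays, so a second measure compared spots position by position, and was chosen after the first was seen. It gave ratios of 1.22 to 3.44 in the same 5 groups and 25.4 without milk at 8 h. All 12 arrays were kept as separate samples, which the series' design text calls biological replicates. Ratios above the spot noise cannot tell separate cultures from separate arrays of the same RNA. In these 5 groups the arrays of a pair differed far less than without milk at 8 h. How much of that difference is spread between cultures is not known, so the p-values may leave some of it out. The pooled spread of the 6-group model also averages over the more variable pair without milk at 8 h.

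The 12 arrays lay on 2 slides. The first slide held the 8 arrays of 3 h and 4 h, and the second the 4 arrays of 8 h. Each milk effect was therefore measured within 1 slide, while the change from 4 h to 8 h and the slide cannot be told apart. Between arms, slide and milk were balanced.

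The alternatives were quantile normalisation, scaling on the median, no scaling, normexp background correction with an offset of 50, the authors' value table, no filter or a stricter filter on dim probes, an intensity trend in the variance, a 2-fold minimum, the replicate number as a block, only the arrays compared, only the arrays of slide 1, and leaving out each array in turn. Scaling on the probes detected on all arrays and scaling on the median of the second set were added later. The fit was tested on simulated data with the real probes' means and spread. For the milk effect at 3 h, over 5041 probes, it recovered 34% of probes changed by 1.5-fold, 60% at 2-fold, 94% at 4-fold and 100% at 8-fold, and 4% of the calls were false. For the average milk effect the recovered shares were 76%, 98%, 100% and 100%, and 4.10% of the calls were false. The simulated arrays had 50 changed probes per fold, noise independent between probes, and no difference between arrays in scaling or detection. Most of the real probes were called, so these false shares do not cover errors that come from the scaling. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, biopython 1.88 and matplotlib 3.10.9.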

Results

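Transcript levels of Lacticaseibacillus casei Zhang, a lactic acid bacterium, were measured on 12 one-colour arrays of 6763 probes. Cells without milk and cells carried in fermented milk were each sampled after 3 h in simulated gastric juice and, later, after 4 h and 8 h of simulated intestinal juice, with 2 arrays per group. The probes carried no gene names, so values are given for groups of probes and for single probes by identifier. On the arrays without milk, between 3154 and 3370 probes were well above background. On the arrays with milk the number was higher, at 4650 to 4907 probes.

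Detection on the arrays without milk divided the probe numbers into 4 consecutive sets. The first set (numbers 1 to 1994, 1994 probes) and the third set (numbers 4809 to 6713, 1905 probes) were mostly not well above background without milk. The second set (numbers 1995 to 4808, 2814 probes) and the fourth set (numbers 6714 to 6763, 50 probes) were mostly well above background there. In the first set, 10.4% ± 2.31 of probes were well above background without milk at 3 h, 9.58% ± 0.709 at 4 h and 10.7% ± 0.851 at 8 h (SD, n = 2 arrays). With milk the share was 96.5% ± 0.355 at 3 h, 92.1% ± 0.780 at 4 h and 81.6% ± 0.461 at 8 h, and each of these differences from the arm without milk exceeded the spread between replicates. In the third set the share lay between 8.95% and 13.4% in all 6 groups. In the second set it lay between 96.4% and 99.6%.

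**Figure D1:**
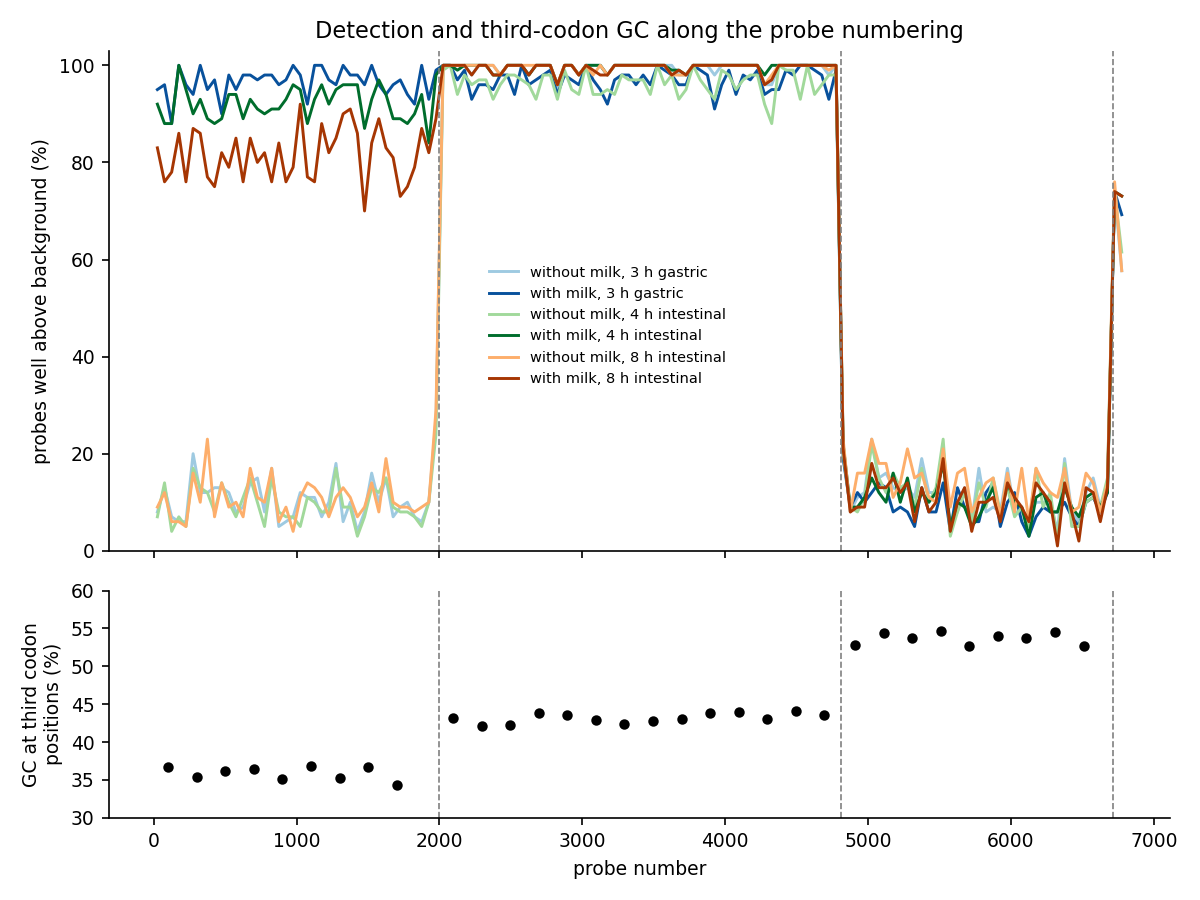
The upper panel plots the percentage of probes well above background along the probe number, in windows of 50 probes, with 1 line per group (mean of 2 arrays), and the lower panel the percentage of G or C at the third codon position, in windows of 200 probes. Dashed lines mark the ends of the sets at 1994, 4808 and 6713, and the first set lies near 10% on the arrays without milk and above 80% on average on those with milk.

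The first set also took most of the signal on the arrays with milk in gastric juice. Its share of the summed processed signal was 8.53% ± 0.743 without milk and 75.5% ± 0.0147 with milk at 3 h. At 4 h these shares were 12.9% ± 0.234 and 35.4% ± 1.43, and at 8 h they were 10.9% ± 2.18 and 22.4% ± 0.621. The share with milk thus fell over the 3 times by more than the spread between replicates. The share of the second set with milk rose from 21.3% ± 0.240 at 3 h to 59.2% ± 1.62 at 4 h and 71.4% ± 0.697 at 8 h. Without milk it was 85.0% ± 1.14, 75.7% ± 0.237 and 81.5% ± 3.28 at the same times. The unscaled median log2 signal of the third set stayed between 1.67 and 2.12 in all groups. The percentage of G or C at the third codon position, read from the open frame of the probes, was 35.03% in the first set, 43.06% in the second set and 54.79% in the third set, with standard errors of 0.250, 0.196 and 0.304 percentage points across probes.

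**Figure D2:**
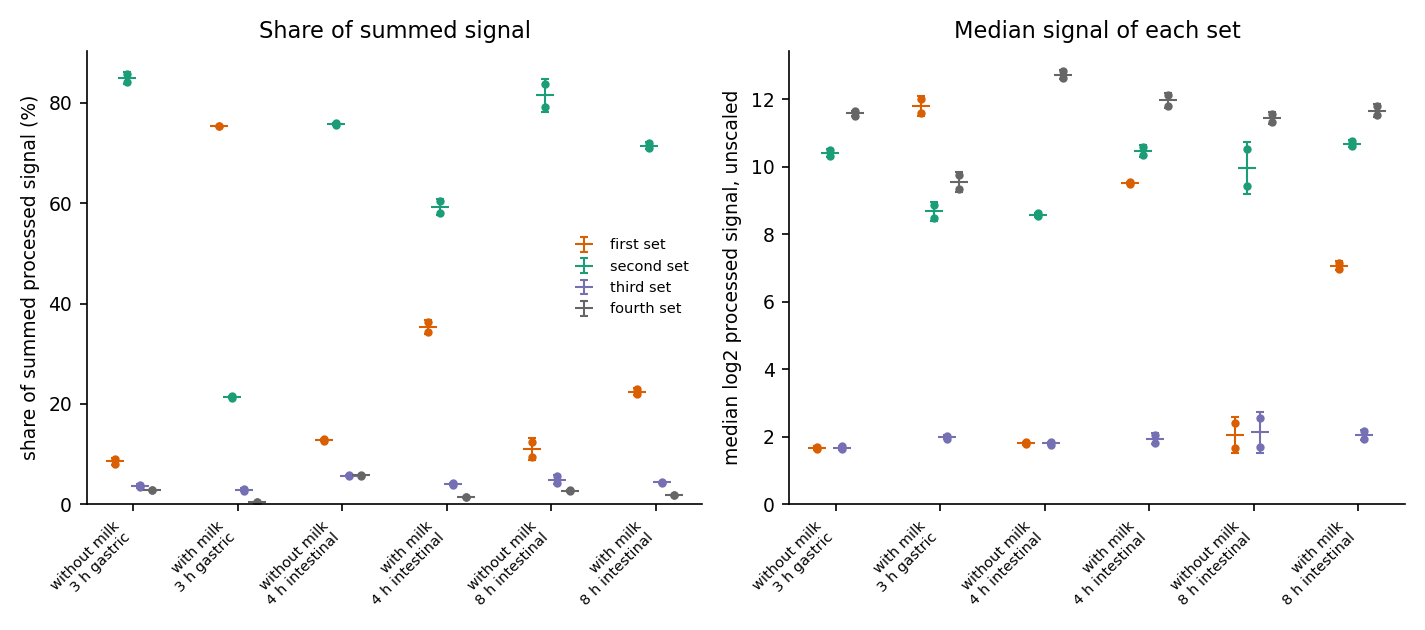
The left panel plots each probe set's percentage of the summed processed signal and the right panel its median log2 processed signal without scaling between arrays, for the 6 groups on the horizontal axis. Points are single arrays and bars the mean ± SD of 2 arrays; the first set holds 75.5% of the signal with milk at 3 h and 8.53% without.

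The first comparison set cells in fermented milk against cells without it after 3 h in gastric juice, the earliest of the 3 times for which the series' design names this contrast. Within the second set, relative to the probes detected on all arrays, 1033 of 2806 probes rose with milk and 1152 fell, of which 628 rose and 735 fell by at least 2-fold. Signals given with a probe are group means of processed signal without scaling between arrays, so their ratio differs from the scaled log2 change beside them. The probe cust_03814 rose by 5.17 log2 units (SE 0.21, adjusted p = 1.52e-07, limma), with unscaled signals of 511 without milk and 6627 with milk, and its sequence was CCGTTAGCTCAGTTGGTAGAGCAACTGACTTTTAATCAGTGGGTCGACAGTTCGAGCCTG. The sources used here name no gene for this probe, and its sequence was not matched to known genes. By its sequence it could report a structural RNA and not a protein-coding gene. A rise of 4.95 log2 units (SE 0.33) was measured for cust_03882, with the sequence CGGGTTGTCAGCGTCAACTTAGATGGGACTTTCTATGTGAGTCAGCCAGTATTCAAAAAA. The largest fall was that of cust_03862, at −7.81 log2 units (SE 0.69, adjusted p = 7.59e-06), with unscaled signals of 19134 and 30.8, and its sequence was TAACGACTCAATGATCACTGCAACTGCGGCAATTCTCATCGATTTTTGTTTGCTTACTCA. The probe cust_03324 had a log2 change of −7.15 (SE 0.37), unscaled signals of 37122 and 94.2, and the sequence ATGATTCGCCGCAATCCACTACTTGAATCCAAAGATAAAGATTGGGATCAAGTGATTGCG. In the first set, 1665 probes were well above background on both arrays with milk and on neither without. Their median bound was at least 309-fold on the main scale, and between 15.1-fold with median scaling and 2040-fold with scaling on the second set's median. The probes cust_01287 and cust_00832 of that set were at least 13511-fold and at least 14828-fold higher with milk on the main scale (adjusted p = 2.81e-12 and 2.51e-12), and at least 661-fold and 725-fold with median scaling. Over all 5041 tested probes on the main scale, 1997 rose and 2812 fell, and the rises were 1904 of the first set, 48 of the second, 43 of the third and 2 of the fourth. With the scaling on probes detected on all arrays, 3162 rose and 1179 fell. The share of rises among the called probes lay between 34.2% and 77.9% over the scalings tried, and in the second set between 1.87% and 57.0%, so the balance of rises and falls depended on the scaling. The median of the second set changed by −2.54 log2 units on the main scale, by −1.54 without scaling and by −0.07 relative to the probes detected on all arrays. The last value was held near 0 by the scaling, since 2643 of the 2866 probes used for it were in the second set.

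After 4 h in the intestinal juice, 1401 of the 2806 second-set probes were higher with milk and 977 lower, 1019 and 703 of them by at least 2-fold. The largest rise was that of cust_03649, at 9.76 log2 units (SE 0.59, adjusted p = 3.44e-07), with unscaled signals of 24.9 without milk and 61721 with milk. Its sequence was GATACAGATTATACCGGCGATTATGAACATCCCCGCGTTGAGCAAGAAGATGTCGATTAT. The probe cust_04592, with the sequence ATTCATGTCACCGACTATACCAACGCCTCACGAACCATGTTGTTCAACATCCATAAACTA, rose by 8.73 log2 units (SE 0.54), with unscaled signals of 16.3 and 19728. The probe cust_02835 fell by 8.28 log2 units (SE 0.36, adjusted p = 5.28e-08), at unscaled signals of 32516 and 299, and had the sequence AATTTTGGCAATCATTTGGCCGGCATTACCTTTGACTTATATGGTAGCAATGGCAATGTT. A log2 change of −7.77 (SE 0.24, unscaled signals 44057 and 578) was measured for cust_02631, with the sequence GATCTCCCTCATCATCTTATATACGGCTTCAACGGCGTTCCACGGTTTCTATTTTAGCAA. In the first set, 1583 probes were well above background only with milk. The median bound was at least 16.4-fold on the main scale, where 1449 of them had a bound above 1-fold, and lay between 1.96-fold with normexp background correction, where 1032 had one, and 138-fold without scaling. On the main scale cust_00276 and cust_00894 were at least 1769-fold and at least 1034-fold higher, and with normexp at least 204-fold and 119-fold. Over all tested probes on the main scale, 2159 rose and 2303 fell. On the scale of the probes detected on all arrays, 3206 rose and 1266 fell, and the share of rises lay between 25.6% and 91.1% over the scalings. In the second set that share lay between 21.7% and 85.7%. The median of the second set changed by −1.17 log2 units on the main scale, by 1.904 without scaling and by 0.39 relative to the probes detected on all arrays.

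After 8 h in the intestinal juice, 667 second-set probes were higher with milk and 898 lower, with 276 and 331 of them at least 2-fold. The probe cust_03059 rose by 5.64 log2 units (SE 0.12, adjusted p = 5.51e-09), at unscaled signals of 182 and 14707, and had the sequence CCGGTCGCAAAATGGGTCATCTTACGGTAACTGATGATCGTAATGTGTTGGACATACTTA. The probe cust_02286 rose by 4.93 log2 units (SE 0.09), at unscaled signals of 88.6 and 4375, and had the sequence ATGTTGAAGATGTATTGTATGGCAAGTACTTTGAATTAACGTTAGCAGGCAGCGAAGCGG. The probes cust_02766 and cust_04125 had log2 changes of −5.42 (SE 0.29) and −5.26 (SE 0.38). Their arrays without milk had SDs of 0.80 and 1.08 on the log2 scale, against 0.07 and 0.05 with milk. In the first set, 1348 probes were well above background only with milk. The median bound was at least 13.6-fold on the main scale, and between 1.48-fold with median scaling and 28.9-fold without scaling. A bound above 1-fold held for 1343 of these probes on the main scale and for 785 with median scaling. The probes cust_01615 and cust_00976 were at least 8314-fold and at least 5441-fold higher on the main scale, and at least 758-fold and 480-fold with normexp. Over all tested probes on the main scale, 1906 rose and 1819 fell. Scaled on the probes detected on all arrays, 2290 rose and 1136 fell, with a share of rises between 19.4% and 93.9% over the scalings and between 19.5% and 88.0% in the second set. The 2 arrays without milk at 8 h differed from each other by at least 2-fold at 356 second-set probes, against 2 to 12 in the other groups. Fitted on the arrays of this comparison alone, 562 second-set probes passed in place of 1565.

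**Figure D3:**
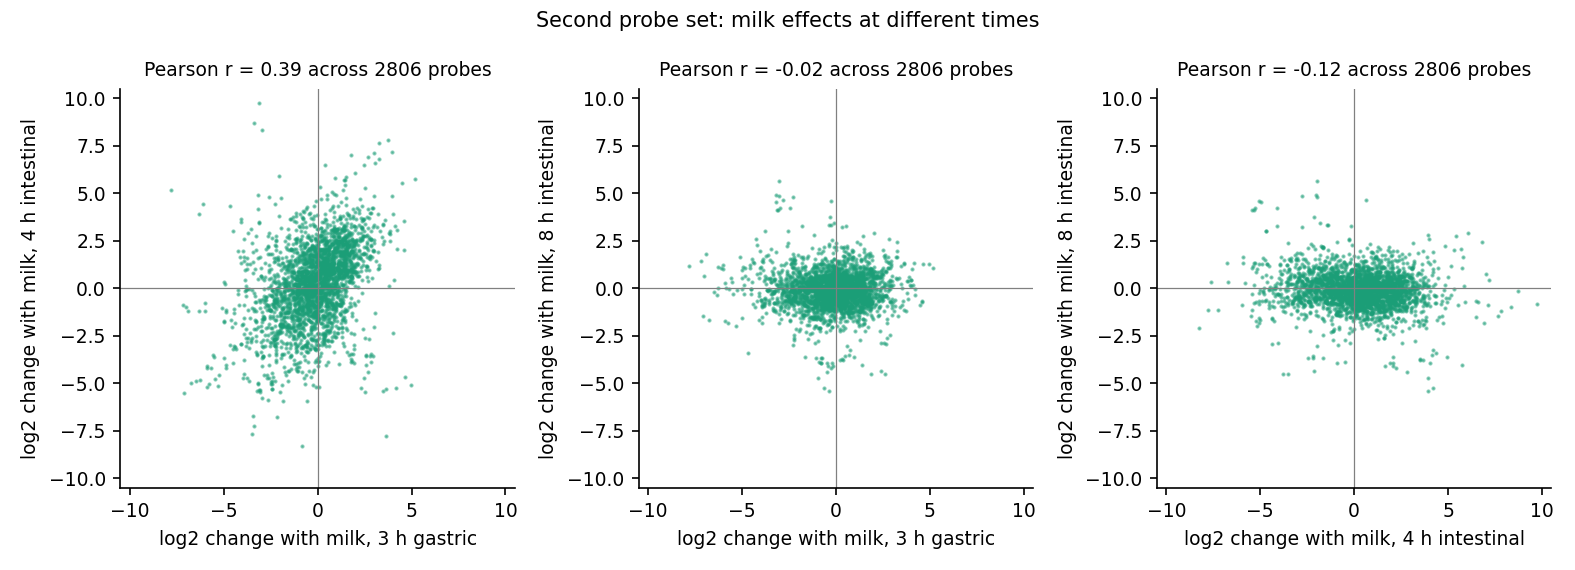
Each point is 1 of 2806 second-set probes, with its log2 change with milk at 1 time on the horizontal and at another on the vertical axis, relative to the probes detected on all arrays. Pearson's r across probes is 0.39 between 3 h and 4 h, −0.02 between 3 h and 8 h and −0.12 between 4 h and 8 h; probes are not independent replicates.

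The time course of the design set 4 h in intestinal juice against 3 h in gastric juice within each arm. Without milk, 782 second-set probes rose and 1419 fell relative to the probes detected on all arrays. The largest rises were those of cust_03029, by 6.86 log2 units (SE 0.18, adjusted p = 9.22e-09), with unscaled signals of 256 and 12076, and cust_04152, by 6.43 (SE 0.24), with 496 and 17436. The largest falls were −9.31 log2 units (SE 0.59) for cust_03649, with unscaled signals of 38822 and 24.9, and −8.87 (SE 0.54) for cust_04592, with 18669 and 16.3. These are the probes with the largest rise with milk at 4 h. Both comparisons use the same arrays without milk at 4 h, so this is not a second observation. With milk, 813 second-set probes rose and 863 fell. The probes cust_03862 and cust_02253 rose with milk by 6.56 (SE 0.69) and 5.45 log2 units (SE 0.78), with unscaled signals of 30.8 and 82.4 at 3 h and 9308 and 11552 at 4 h. Log2 changes of −7.54 (SE 0.33) and −7.28 (SE 0.29) were measured for cust_03882 and cust_03190, whose unscaled signals were 15291 and 14325 at 3 h and 264 and 296 at 4 h.

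On the main scale over all tested probes, 3354 rose and 988 fell without milk from 3 h to 4 h. Of the rises, 1662 were of probes not well above background on any of the 4 arrays, 1601 of them in the first set, and without such probes 1692 rose and 988 fell. With milk, 2590 rose and 1936 fell, and the first set gave 28 rises and 1790 falls and the second 2463 rises and 94 falls. The first-set probes cust_00089 and cust_01847 had log2 changes with milk of −8.00 (SE 0.16) and −7.21 (SE 0.29), with unscaled signals of 8473 and 2619 at 3 h and 37.7 and 20.1 at 4 h. The counts scaled on the probes detected on all arrays were 2838 rises and 1426 falls without milk, and 844 and 2985 with milk. Of those 2838 rises, 1631 were of probes not well above background on any array compared, and without such probes 1207 rose and 1426 fell without milk. The share of rises lay between 11.0% and 80.6% without milk and between 19.2% and 60.5% with milk over the scalings, and in the second set between 9.14% and 54.6% and between 32.6% and 97.8%.

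From 4 h to 8 h of intestinal juice, 1514 second-set probes rose and 761 fell without milk, and 937 rose and 772 fell with milk. Without milk, cust_02823 rose by 8.07 log2 units (SE 0.12, adjusted p = 8.88e-10), with unscaled signals of 34.5 and 16090. The probe cust_03649 rose by 8.29 log2 units (SE 0.59), with an SD of 1.72 between its 2 arrays at 8 h. The largest falls without milk were −6.37 (SE 0.17) for cust_03387 and −6.32 (SE 0.12) for cust_02175, with unscaled signals of 16633 and 20644 at 4 h and 350 and 451 at 8 h. With milk, the probes cust_02631 and cust_02944 rose by 4.87 (SE 0.24) and 4.80 log2 units (SE 0.11), with unscaled signals of 578 and 258 at 4 h and 16659 and 7093 at 8 h. The falls of cust_02763 and cust_02360 with milk were −3.94 (SE 0.11) and −3.84 (SE 0.11), with unscaled signals of 25483 and 24070 at 4 h and 1640 and 1655 at 8 h.

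On the main scale over all tested probes, 1110 rose and 3025 fell without milk from 4 h to 8 h, of which 1449 calls were of probes not well above background on any of the 4 arrays; without these 1106 rose and 1580 fell. The first-set probe cust_00813 was at least 181-fold higher without milk at 8 h than at 4 h (adjusted p = 7.62e-08; at least 19.5-fold with normexp), with unscaled signals of 3.13 at 4 h and 3223 at 8 h. With milk, 1682 rose and 1876 fell, with 47 rises and 1590 falls in the first set and 1550 rises and 269 falls in the second. Scaled on the probes detected on all arrays, 1630 rose and 2067 fell without milk, and 972 and 2566 with milk. On that scale 26 of the rises and 1027 of the falls without milk were of probes not well above background on any array compared, and without these 1604 rose and 1040 fell. The share of rises lay between 20.8% and 83.3% without milk and between 19.8% and 60.9% with milk over the scalings, and in the second set between 47.4% and 85.3% and between 39.6% and 84.7%. The 4 h and 8 h arrays lay on different slides, so this change and the slide cannot be told apart.

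Whether the milk effect differed between times was tested as a difference of effects. Between 3 h in gastric and 4 h in intestinal juice, the milk effect of 2011 of the 2806 second-set probes differed, upward at 4 h for 1267 and downward for 744. In gastric juice, cust_03862 was at −5.58 ± 0.11 with milk and 2.23 ± 0.37 without (mean log2 relative to the probes detected on all arrays ± SD, n = 2), and at 4 h it was at 0.97 ± 0.18 with milk and −4.21 ± 0.02 without. Its milk effect differed by 12.995 log2 units (SE 0.98, adjusted p = 2.90e-06). The probe cust_03649 went the same way, from 0.13 ± 0.01 with milk and 3.25 ± 0.09 without at 3 h to 3.70 ± 0.07 and −6.06 ± 0.17 at 4 h, a difference of 12.88 log2 units (SE 0.83). The opposite turn was measured for cust_02631, which was at 2.43 ± 0.01 with milk and −1.22 ± 0.48 without at 3 h and at −3.04 ± 0.04 and 4.73 ± 0.00 at 4 h, a difference of −11.42 (SE 0.35). For cust_03882 the difference was −10.01 (SE 0.47). Over all tested probes on the main scale 4406 differed, 1886 upward and 2520 downward, with 1902 of the downward ones in the first set. Of these, 1602 were of probes not well above background without milk at either time, so they are taken against background values. The median of the first set without milk moved from 3 h to 4 h by 2.01 log2 units on the main scale and by 0.12 without scaling, so the scaling of background set part of these differences. Without scaling 1643 first-set probes differed downward. On the scale of the probes detected on all arrays, 1284 differed upward and 2923 downward, and the upward share lay between 20.9% and 60.02% over the scalings and between 43.9% and 97.9% in the second set.

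Between 4 h and 8 h of intestinal juice, the milk effect of 2244 second-set probes differed, upward at 8 h for 894 and downward for 1350. The probe cust_02944, with the sequence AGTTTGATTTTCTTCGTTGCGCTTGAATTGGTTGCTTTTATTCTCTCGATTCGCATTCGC, was at −4.20 ± 0.12 with milk and 0.88 ± 0.04 without at 4 h, and at 0.60 ± 0.01 with milk and −4.02 ± 0.08 without at 8 h. Its milk effect differed by 9.71 log2 units (SE 0.16, adjusted p = 1.18e-09). The probe cust_03839 differed by 9.56 log2 units (SE 0.28), and had the sequence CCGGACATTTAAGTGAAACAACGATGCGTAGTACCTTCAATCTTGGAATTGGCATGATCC. The opposite turn was measured for cust_02823, with the sequence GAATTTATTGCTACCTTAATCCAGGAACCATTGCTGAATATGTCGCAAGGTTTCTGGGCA, which was at 0.13 ± 0.14 with milk and −5.59 ± 0.00 without at 4 h and at −1.56 ± 0.01 and 2.48 ± 0.20 at 8 h, a difference of −9.76 (SE 0.17). For cust_03649 it was −10.58 (SE 0.83). Over all tested probes on the main scale 3493 differed, 1951 upward and 1542 downward, and of these 206 and 690 were first-set probes not well above background without milk at either time. Among the downward ones was the first-set probe cust_01006, which was not well above background without milk at 4 h, with an unscaled signal of 3.70 against 35376 with milk, and had 1950 without milk and 3075 with milk at 8 h. Relative to the probes detected on all arrays, 1052 differed upward and 2852 downward, and the upward share lay between 13.7% and 63.7% over the scalings and between 23.7% and 66.9% in the second set. The 4 h and 8 h effects were each measured within a slide, but on different slides.

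**Figure D4:**
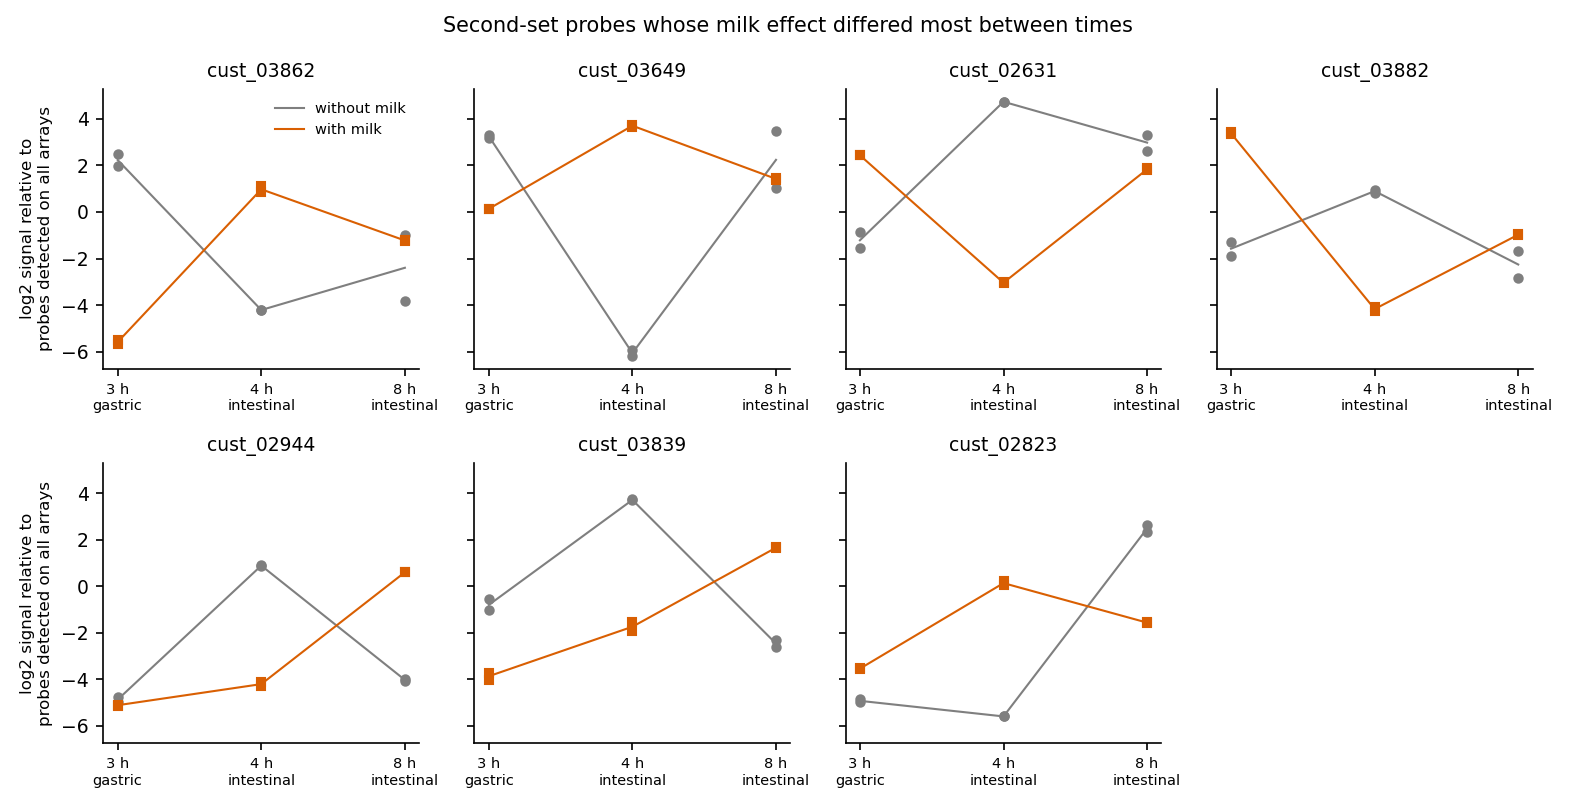
Log2 signal relative to the probes detected on all arrays of the 7 second-set probes named for differences of milk effects, at the 3 times on the horizontal axis; points are single arrays and lines join the means of 2 arrays without milk (grey) and with milk (orange). The lines of cust_03862 cross between 3 h and 4 h, from −5.58 with milk and 2.23 without to 0.97 and −4.21.

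The last comparison averaged the milk effect over the 3 times, 6 arrays with milk against 6 without. In the second set, 485 of 2806 probes rose and 444 fell relative to the probes detected on all arrays. The probes cust_02091 and cust_03814 rose by 4.16 (SE 0.61, adjusted p = 0.00175) and 3.99 log2 units (SE 0.66). At 3 h, 4 h and 8 h, cust_02091 was at −3.93 ± 0.12, −6.43 ± 0.07 and −3.24 ± 0.61 without milk and at −0.67 ± 0.07, 0.36 ± 0.09 and −0.81 ± 0.01 with milk (SD, n = 2). The probes cust_02685 and cust_03919 had log2 changes of −4.69 (SE 0.82) and −4.48 (SE 0.78, adjusted p = 0.00343). With milk, cust_03919 was well above background on 4 of 6 arrays, and its unscaled signal at 3 h was 13.2, so its change rests in part on values not well above background. Of the first set, 1643 of 1923 tested probes rose and 12 fell on the main scale, and cust_01287 and cust_00276 were at least 3825-fold and at least 3234-fold higher with milk, or at least 348-fold and 294-fold with median scaling. Over all tested probes on that scale 1683 rose and 2118 fell. Scaled on the probes detected on all arrays, 2272 rose and 497 fell, with a share of rises between 25.4% and 93.7% over the scalings and between 1.54% and 70.8% in the second set. Leaving out any 1 of the 4 arrays of 4 h took the second-set count from 929 to between 562 and 575. With 1 mean per group in place of additive terms, it was 2280. Without scaling 34 second-set probes rose and 14 fell, and with the 75th percentile over all probes 30 rose and 1917 fell.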

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

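The tests of differences below were planned for all probes, and their restriction to the second set, as well as the look at control probes, was chosen after results were seen. The milk effect differed between 3 h in gastric and 4 h in intestinal juice for 4406 of all tested probes on the main scale, and between 4 h and 8 h for 3493. At 4 h against 3 h, 1602 of these were first-set probes not well above background without milk, so their differences are taken against background values. In the second set, relative to the probes detected on all arrays, the milk effect of 2011 probes differed between 3 h and 4 h and that of 2244 between 4 h and 8 h (limma, adjusted p under 0.05).

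Of single second-set probes, cust_03862 and cust_03649 had the largest upward differences of the milk effect at 4 h against 3 h, at 12.995 and 12.88 log2 units, and cust_02631 and cust_03882 the largest downward ones, at −11.42 and −10.01. At 8 h against 4 h the largest upward differences were 9.71 for cust_02944 and 9.56 for cust_03839, and the largest downward ones −10.58 for cust_03649 and −9.76 for cust_02823. Both differences of cust_03649 contain its milk effect at 4 h, so they are not independent of each other. In every case named here the mean milk effect had opposite signs at the times compared, but that of cust_03649 at 8 h lay within the SD of 1.72 between its arrays without milk.

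One signal lay outside the probes tested. Among 60 control probes, ETG04_27747 was well above background only on arrays with milk at all 3 times, and 3 others at 1 or 2 of them. At 3 h its log2 signal was 10.86 ± 0.13 with milk and 2.79 ± 0.34 without (SD, n = 2), a difference of 8.06, and the difference was 6.58 at 4 h and 4.89 at 8 h. Its mean signal with milk was 1855 at 3 h, 962 at 4 h and 402 at 8 h, against 6.94, 10.0 and 13.5 without milk.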

How the results depend on the processing

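The alternatives on second-set probes alone, and the scaling on probes detected on all arrays or on the second set's median, were chosen after results were seen. Over 26 counts and shares, 221 of 251 values under other settings stayed within 1.5 times the main count or within 1 SD, and 120 of 124 values with 1 array left out did so. Counts carry no direction, and the balance of rises and falls did turn with the scaling. At 3 h the share of rises over all probes was 41.5% on the main scale and up to 77.9% on others, and from gastric to intestinal juice without milk 77.2% and down to 11.0%. The 80 named values kept their direction and their side of the threshold under all 882 other settings and all 448 fits with 1 array left out. They were picked as the largest called changes, so this was likely in advance and does not extend to other probes. Bounds moved with the scaling: the median bound of the first set at 3 h was 309-fold on the main scale and 15.1-fold with median scaling. First-set probes with a bound above 1-fold numbered 1343 of 1348 at 8 h on the main scale and 785 with median scaling, and at 4 h 1449 of 1583 and 1032 with normexp. Signal over background is one limit, since probes not well above background on the arrays without milk have only bounds. The scaling and the 2 arrays per group are others.

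Testing only the 2866 probes well above background on all arrays called 2705, 2468 and 1835 probes for the milk effect at 3 h, 4 h and 8 h. For gastric to intestinal juice it called 2251 without milk and 2579 with milk, for 4 h to 8 h it called 2289 and 1857, for the 2 differences of milk effects 2315 and 2240, and for the average 2010. Fewer probes were tested here, and the filter also changed which ones: 91 of the 2866 were in the first set, against 1923 of the 5041 in the main fit. How much each of these lowered the counts was not tested. From gastric to intestinal juice without milk, the main 4342 became 2330 with quantile normalisation, 2628 with median scaling, 2289 without scaling and 2340 with the authors' value table, where the main count held 1662 probes not well above background on any array compared. Without scaling, the change from 4 h to 8 h without milk called 2390 and the average milk effect 2273, and the cause was not tested.

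In the second set, a 2-fold minimum left 1363 probes at 3 h, 607 at 8 h, 766 from gastric to intestinal juice with milk and 785 from 4 h to 8 h with milk. The 8 h milk effect called 966 without scaling and 562 with only the arrays compared, where 2 arrays per group leave a less precise spread and the pair without milk is the most variable. From gastric to intestinal juice with milk the 75th percentile over all probes called 2570, and from 4 h to 8 h with milk no scaling called 802. The average milk effect called 1947 with the 75th percentile over all probes, 48 without scaling, 1741 with the authors' table rescaled and 2280 with 1 mean per group. The cause was not tested for these scalings. The 929 calls of the average ranged from 562 to 1234 with 1 array left out; they were 568 and 562 without array 1 or 2 of 4 h without milk, and 566 and 575 without array 1 or 2 of 4 h with milk. With no background subtracted, the first set's share of the signal was 13.3% without milk at 4 h and 74.98% with milk at 3 h.

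The replicate number as a block gave 4811, 4455 and 3710 calls for the milk effect at 3 h, 4 h and 8 h, 3662 for the average and 756 for the average in the second set, and changed no count by over 1.5 times. Over the 15 pairs of groups the deviations of same-numbered arrays correlated at −0.0904 to 0.110 across probes. The 2 pairs above 0.1 were consecutive times within an arm: 4 h and 8 h without milk (0.104), and 3 h and 4 h with milk (0.110). The pair of 3 h and 4 h without milk was at 0.0426, and that of 4 h and 8 h with milk at −0.0716. Such weak correlations, from 2 arrays per group, cannot decide whether the numbers pair the samples. Slide as a block leaves each milk effect as it is, since both arms lie on the same slide. Within slide 1 alone the milk effect called 4890 probes at 3 h and 4673 at 4 h, and within slide 2 alone 2878 at 8 h. The merging of several probes per gene and the gene lists were not run, since the probes carry no gene names.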

Other observations

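Chosen before their results were seen were the tests of a mislabelled array, of the 3 h to 4 h course, of neighbouring probe numbers and of the relation between 3 h and 4 h; all other tests here, the peptide lists included, were chosen after. Milk effects in gastric and early intestinal juice were correlated in part. Across the 2806 second-set probes, the effect at 3 h correlated with that at 4 h at r = 0.39 (rho = 0.42), with no array in common. There were 743 probes higher with milk at both times against 516 expected for independent lists, and 579 lower at both against 401. A rise at 3 h with a fall at 4 h was called for 204 probes, against 360 expected. The reverse was called for 361, against 575 expected. The effect still differed in size or direction between 3 h and 4 h at 2011 probes, so it was not a single unchanged response. The 8 h effect had r = −0.02 with 3 h and −0.12 with 4 h. A hypothesis is that part of a response to milk, or to growth in it, was shared between gastric and early intestinal juice. Whether the RNA read by the first set with milk also bound second-set probes was not tested. The correlation therefore does not single out a response of the cells. The correlation of 0.39 was above the bound of 0.3 set for it, but probes are not independent replicates. Whether such a part lasted to 8 h was not decided, since the 8 h effect lies on another slide and rests on the most variable pair. At all 3 times 170 probes rose, against 123 expected, and 139 fell, against 128. These expected counts take the 3 times as independent, although 3 h and 4 h were correlated. They therefore do not show an effect that lasted to 8 h.

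The course in intestinal juice differed between arms. From 4 h to 8 h, the changes without milk and with milk correlated at r = −0.39 across second-set probes, where 535 rose without milk and fell with it against 417 expected, and 413 did the opposite against 254. From gastric to intestinal juice the 2 arms correlated at r = 0.03. These were 2 of 5 relations computed, with no array in common within a relation, and both arms crossed the same pair of slides. Second-set probes whose peptide was membrane-like (135) or strongly charged (47) were not shown to stand apart from the rest. At 3 h, 60 membrane-like probes rose and 47 fell (camera, adjusted p = 0.241; 0.545 with an estimated correlation), and 15 charged probes rose and 18 fell (camera, adjusted p = 0.732; 0.810 with an estimated correlation). The smallest camera adjusted p over the 7 comparisons was 0.142.

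The signal of the first probe set on arrays with milk is the pattern that shapes most of the counts. Several explanations have values against them. A general rise in background would lift the third set too, whose median rose by at most 0.303 log2 units without scaling. Cross-hybridisation of second-set transcripts would light the first set without milk as well, where the highest group mean of probes well above background was 10.7%, and the highest single array 11.99%. Induction of genes like those of the second set would need a similar base composition, but the highest window of the first set lay 5.30 percentage points below the lowest of the second in third-position GC. What stays open is RNA of another organism that came with the milk: read from sequence alone, third-position GC changes within 10 probe numbers of each end of the second set, whose ends came from detection without milk. Which organism it could be was not tested, the labels name no other one, and induction of genes of the strain itself with an unlike base composition stays untested. A minority of the set had signal without milk: 138 to 150 probes were well above background on all 4 arrays of a time. The probes cust_00813 and cust_01006 were so on neither array without milk at 4 h and on both at 8 h. RNA brought by the milk does not account for these, and cross-hybridisation stays open for them.

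The second set looked lower with milk when arrays were scaled over all probes, by a median of −2.54, −1.17 and −0.48 log2 units at 3 h, 4 h and 8 h. Without scaling, its median was higher with milk at 4 h, by 1.904 log2 units, so at this time the lower level may come from a percentile that counts the first set. At 8 h it was higher by 0.60 log2 units. The unscaled medians of the single arrays at 8 h were 9.43 and 10.52 without milk, and 10.76 and 10.62 with milk. The rise at 8 h lay within the SD of 0.771 between the arrays without milk, so it does not decide the reading at that time. At 3 h the unscaled median was also lower, at −1.54, which lies between the bounds set for either reading. Per the labels, equal amounts of total RNA were labelled, so other RNA in a sample would lower the second set's signal too, and this cannot be told apart from a lower level in the cells.

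The 2 arrays without milk at 8 h differed by an SD of 0.72 log2 units across second-set probes, with 243 probes at least 2-fold higher on array 1 and 113 on array 2. Spot noise or a slide effect meets a value against it: the variance of the difference was 25.4 times the spot noise, and 1.22 times for the pair with milk on the same slide. A wrong label also does: each array correlated best with its partner, by a margin in r of at least 0.0282. Cultures caught at different points of the change from 3 h to 4 h would show that change in their difference, but the correlation was 0.0647. With the 4 h to 8 h change with milk it was 0.151, and outside their group array 1 correlated best with an array with milk at 8 h and array 2 with an array with milk at 4 h, so different points of a change within intestinal juice stay open. Other array-wide technical differences stay open, and some values go with them. Array 2 was brighter than array 1 at 57 of 60 control probes, by a median of 0.65 log2 units without scaling, while medians in the other groups lay between −0.22 and 0.02. The unscaled median of the third set was 2.55 on array 2 and 1.70 on array 1, with 298 against 213 probes well above background. Whether labelling, hybridisation or background on array 2 produced the scatter in both directions was not tested, and a biological difference between the 2 cultures stays open and untested too.

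In bacteria, neighbouring genes often share a transcript, so neighbouring probe numbers might change together if numbers followed gene order. Milk effects of consecutive numbers had correlations no higher than those of shuffled numbers at any of the 3 times (lowest −0.0309, highest of 1000 shuffles 0.0534 to 0.0665), so no such order was seen. Probes near each other on the array but over 50 numbers apart had correlations of at most 0.00570, so there was no pattern for array position to explain.

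For the average milk effect, splits of the arrays could not exclude chance. Shares under 0.05 were reached only on splits of single arrays, most of which part near-identical arrays. Of 100 splits of the 12 arrays into 6 and 6, drawn with the real one, 1 gave as many calls, the real split with 3801, and the highest other gave 2847. In the second set 2 of 100 splits gave 929 or more, the real one included, and the highest other gave 1068. Most of these splits part the 2 arrays of a group, whose difference had 1.22 to 3.44 times the variance of spot noise in 5 groups, so they are a weak comparison. With pairs kept whole and each time divided between the sides there are 4 splits, too few for a share under 0.05. Over all probes the real one gave 3801 and the highest other 168. Among second-set probes it gave 929 and the highest other 1068. The other 6 splits that keep pairs whole put both groups of a time on 1 side, so that with time in the model each compares the arms at 1 time alone. They gave up to 3871 calls over all probes and up to 1403 in the second set, and with them 3 and 4 of 10 splits reached the real count. The split with 1068 exchanged the 4 arrays of 8 h, which are the arrays of slide 2, between the arms. A milk effect that differs at 8 h cannot be told apart here from effects of the slide or of the variable pair without milk. Within slide 2 the milk effect called 562 second-set probes in a fit of its own arrays.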
